A study of Arabidopsis thaliana with 3 samples.

How the data were processed

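Flower buds of the Arabidopsis thaliana ap1 mutant were compared with buds of the wild type Ler (Landsberg erecta, a laboratory strain) on 3 Agilent 2-colour microarrays. Per the labels' protocols, plants grew under continuous light at 21°C, each sample pooled buds of stages 1 to 13 from about 50 plants, and RNA came from 100 mg of tissue. Each array held 1 of 3 independent sets, collected on different days at 1 time of day, so a set is the replicate and n = 3. The ap1 RNA carried Cy5 in set 1 and Cy3 in sets 2 and 3. The array names in the labels place sets 1 and 2 on slide 1 and set 3 on slide 2.

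The deposited values are log ratios, 1 for each of 32672 rows and each array, with a further table of the authors' combined ratio of the 3 arrays. The software, background correction and dye normalization behind the deposited log10 ratios are not given in the sources used here, and neither is the log base. The labels name a scanner protocol of Agilent's Feature Extraction software, which writes log10 ratios, so the values were read as log10 and multiplied by 3.32 to give log2. Every fold below rests on this reading, as do counts and shares at a fold cut and the test against 1.2-fold. The other limma tests do not depend on it. The deposited tables hold no signal per channel, so no filter on dim probes and no trend of variance on signal could be applied. The small number of arrays is a further limit on the precision.

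Direction was settled in part. In 23 of the 29 control rows other than spike-ins that had a ratio on all 3 arrays, set 1 was opposite in sign to sets 2 and 3. Control spots, taken here to have no plant target, can follow the dye but not the genotype. The columns were therefore taken as already turned to run by sample and were left as deposited. This use of control rows was chosen after the values were seen. The rule fixed beforehand turned the ratios if set 1 ran against sets 2 and 3, and left them if all ran alike. Where labels, headers and columns left the direction unsettled, it gave sizes and counts without a direction. Set 1 had an r of -0.129 with set 2 and -0.0641 with set 3 across probes. Leaving the columns unturned and giving counts of higher and lower probes therefore departs from that rule. The labels name set 1 as Ler versus ap1 and sets 2 and 3 as ap1 versus Ler. The authors' combined ratio is named as ap1 versus Ler. Across the tested probes it rose with each of the 3 columns (least-squares weights 0.213, 0.273 and 0.394 for sets 1, 2 and 3). These weights are a fit over all tested probes, and the mix differed from probe to probe. Positive values are therefore taken as higher in ap1. This direction is likely rather than stated, and if the name means the inverse ratio, every "higher" becomes "lower".

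Between 22.2% and 25.2% of the 32615 probes on an array had a ratio of exactly 0, against 14 to 20 probes per array with a non-zero deposited value under 0.0001 in size. An exact 0 was read as no ratio, because Feature Extraction writes 0 where neither channel exceeds background. The 23174 probes (71.1%) with a ratio on all 3 arrays were tested. Another 1486 had a ratio on 2 arrays, 2201 on 1 and 5754 on none. The 57 control rows were left out of the tests. The medians of the tested probes were 0.06, -0.0028 and 0.0064 on the log2 scale for sets 1, 2 and 3, and the median of the authors' combined ratio was 0.02. No column of other samples was present (0 columns left unused).

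The tables used here pair no probe with a gene. The AP1 transcript, the 15 fixed genes and the 20 gene lists chosen before the data were examined could therefore not be tested, and the unit of every result is the probe. For the same reason the naming rule (the largest changes of 1 sign on all 3 arrays) was held to 2 probes in each direction. No genome position is known for them here.

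Tests were made in R 4.3.3 with limma 3.58.1. The main test, chosen before the data were examined, was lmFit with an intercept only on the 3 log2 ratios of each probe, followed by eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 array of one dye orientation and 2 of the other, this mean keeps part of any dye effect, so a second fit, also chosen before the data were examined, added the dye orientation as a term. Its ap1 coefficient weighs both orientations equally and is called the dye-balanced estimate. The dye component is the other coefficient, positive where set 1 exceeded sets 2 and 3. On the log2 scale set 1 differed from the mean of sets 2 and 3 by 2 times the dye component. The dye component cannot be separated from any difference peculiar to set 1. As the only array of its orientation, set 1 is fitted exactly in this second fit, which leaves 1 residual degree of freedom, from sets 2 and 3. Its p-values therefore take no account of spread among arrays of the orientation of set 1. Correlations between arrays are across probes, which are not independent replicates, with 95% intervals from 1000 bootstrap draws over probes. Intervals for shares of probes or control rows are exact binomial. They count probes or rows as independent and hold no spread among sets. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

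The procedure was tested on simulated data for this comparison, in 10 simulations of 23174 probes, 200 of them changed. Noise was drawn from the dye-term fit and hence from sets 2 and 3. The variance of a probe was drawn independently of its change, so the shares recovered below need not hold for the real arrays. Dye effects, where added, were the fitted values, which already hold the noise of set 1. With no dye effect, the main test recovered 50.6% of 2-fold, 89.7% of 4-fold and 97.9% of 16-fold changes. With dye effects of the size estimated from the arrays it recovered 0%, 1.79% and 65.2%, and the fit with a dye term recovered 0.299%, 66.7% and 93.9%. Alternatives were each set left out in turn, centring and scaling of arrays, array weights, robust eBayes, a test against 1.2-fold, other thresholds, and probes with ratios on at least 2 arrays. Keeping exact zeros, an adjusted p of 0.1, rank correlation and reading the values as log2 were added after seeing the data.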

Results

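Transcript levels in flower buds of the ap1 mutant were compared with those of Ler wild type. AP1 (APETALA1) encodes a MADS-box transcription factor required for floral meristem identity and for sepal and petal identity. The data comprised 3 microarrays, each with ap1 and Ler RNA of 1 independent set labelled in opposite colours. Of 32615 probes, 23174 had a ratio on all 3 arrays. All ratios are given as ap1 over Ler, which is the likely direction, and folds assume that the deposited values are log10.

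The arrays were first compared with each other. Sets 2 and 3, both with ap1 in Cy3, gave alike ratios, with a Pearson r of 0.768 across probes (95% interval 0.758 to 0.778). Set 1, the only array with ap1 in Cy5, did not share this pattern. Over all tested probes its r was -0.129 with set 2 (-0.153 to -0.102) and -0.0641 with set 3 (-0.0884 to -0.0396). These negative values came mostly from the smaller of the 2 series into which the probe identifiers fall. Across the 1492 tested probes of the smaller series r was -0.702 with set 2 and -0.631 with set 3. Across the 21682 of the larger series it was -0.0520 with set 2 (-0.0763 to -0.0263) and 0.0189 with set 3 (-0.00589 to 0.0441). All 3 signs were equal for 9315 probes (40.2%), and set 1 was the odd one out for 9044 (39.0%). Set 2 was the odd one for 2630 (11.3%) and set 3 for 2185 (9.43%). Independent signs would give 25% for each pattern.

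**Figure D1:**
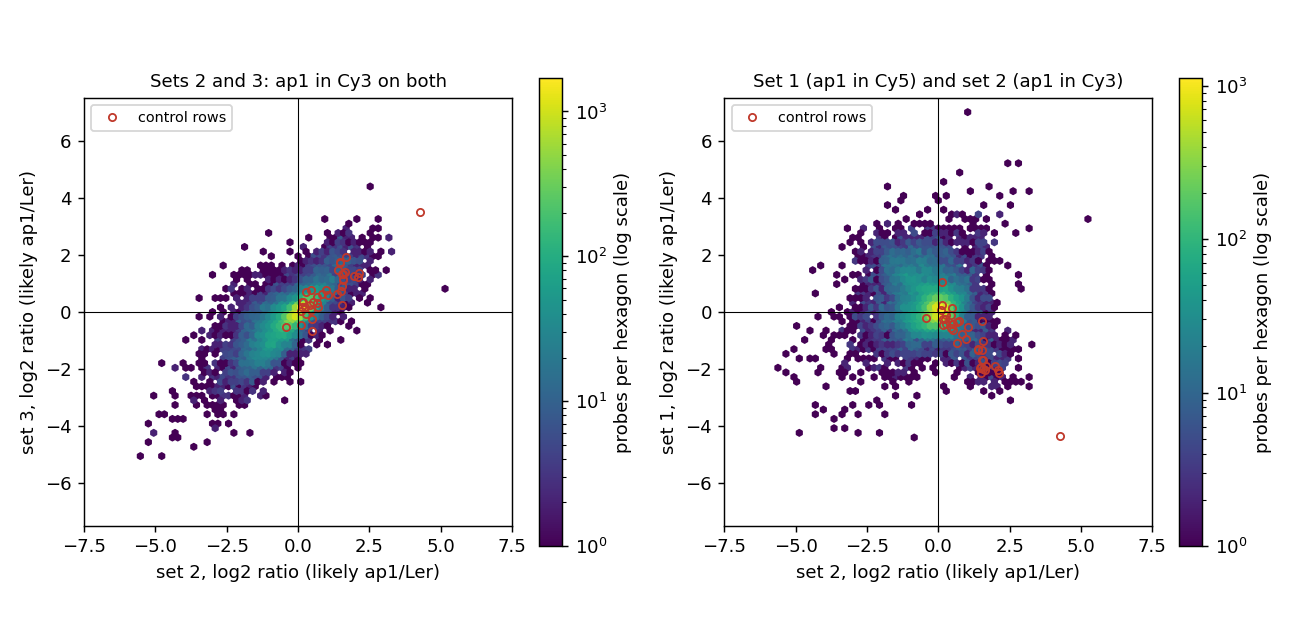
Log2 ratios of the 23174 tested probes on sets 2 and 3 (left) and on sets 2 and 1 (right), as the number of probes per hexagon on a log colour scale, with the 38 control rows measured on all arrays as red circles. Sets 2 and 3 follow 1 line (r = 0.768), whereas in the right panel (r = -0.129) 31 of the control rows have set 1 opposite in sign to sets 2 and 3.

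The question of the study's only comparison was which transcripts differ between ap1 and wild-type buds. On all 3 independent sets, 263 probes (1.13% of those tested) differed by at least 2-fold in 1 direction. Of these, 119 had more signal in ap1, with a median mean log2 ratio of 1.83, and 144 had less, with a median of -1.86. At 4-fold or more on every set there were 30 probes, 8 with more and 22 with less signal in ap1. At 8-fold there were 5, all with less signal in ap1. If 1 array is turned in sign, 2-fold differences of 1 direction on all 3 arrays number 597 with set 1 turned, 15 with set 2 turned and 4 with set 3 turned. Without set 1, sets 2 and 3 shared 1673 probes at 2-fold in 1 direction, 437 with more and 1236 with less signal in ap1.

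None of these differences passed the main test. With limma and Benjamini-Hochberg adjustment, 0 of 23174 probes reached the threshold of 0.05, and the smallest adjusted p was 0.236. Before adjustment, 3308 probes lay under 0.05, of which 1519 had more and 1789 less signal in ap1 (5% of all tests would be 1159). In simulations with dye effects of the estimated size, this test put 1.29% of unchanged probes under 0.05. Those effects already hold the noise of set 1, so this share does not measure the null rate on the real arrays. The 3308 became 7675 without set 1, 1125 without set 2 and 1059 without set 3. With the dye orientation as a term the count at the threshold was also 0, with a smallest adjusted p of 0.0646 and 6112 probes under 0.05 before adjustment. Set 1 is fitted exactly there, so the error of that fit comes from sets 2 and 3 alone and holds none of the spread of set 1. In the same fit the dye component was at least 2-fold on 1846 probes, against 945 for the dye-balanced estimate. Without set 1 the test called 1894 probes, 489 higher and 1405 lower, but then both arrays had ap1 in Cy3, so genotype and dye cannot be told apart.

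The probes named below showed the widest differences of 1 sign on all sets. CUST_3261_PI355422546 had the lowest mean, at -4.74 ± 0.42 on the log2 scale (SD, n = 3), or 26.7-fold less signal in ap1. Its sets gave -4.28, -4.84 and -5.10, and its adjusted p was 0.236 in the main limma fit. CUST_21409_PI355422546 followed at -4.21 ± 1.99 (SD, n = 3), with -1.93 on set 1 against -5.57 and -5.14 on sets 2 and 3. Its adjusted p was 0.275 in the main limma fit, its dye-balanced estimate was -3.64, and without set 1 its mean was -5.35. CUST_13377_PI355422546 had the highest mean, 3.56 ± 1.51 (SD, n = 3), or 11.8-fold more signal in ap1. Its sets gave 5.30, 2.80 and 2.59, with an adjusted p of 0.263 by limma, a dye-balanced estimate of 3.998 and a mean of 2.70 without set 1. CUST_4262_PI355422546 stood at 3.56 ± 0.96 (SD, n = 3), with 3.66, 2.55 and 4.45 on the 3 sets. Its adjusted p was 0.241 by limma, its dye-balanced estimate was 3.58, and its dye component of 0.08 was the smallest of the 4 probes.

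**Figure D2:**
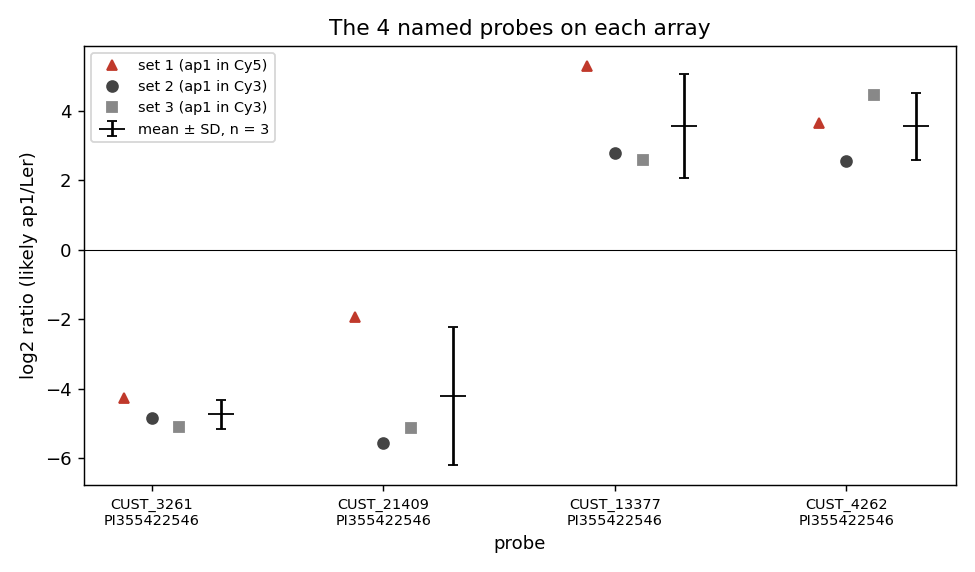
Log2 ratio of the 4 named probes on each array (red triangles, set 1 with ap1 in Cy5; circles and squares, sets 2 and 3 with ap1 in Cy3), with the mean and SD of the 3 sets. All 3 sets lie on the same side of 0 for each probe, and set 1 stands apart for CUST_21409_PI355422546 (-1.93) and CUST_13377_PI355422546 (5.30).

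The balance of higher and lower probes depended on how the arrays were weighed. In the dye-balanced estimate, 945 probes reached 2-fold, 483 with more and 462 with less signal in ap1, so that 48.9% were lower (exact 95% interval 45.7 to 52.1%). At 4-fold or more it held 130 probes, 66 higher and 64 lower (49.2% lower). At 8-fold or more it held 27 probes, 9 higher and 18 lower (66.7% lower, exact 95% interval 46.0 to 83.5%). Both intervals count probes as independent and hold no spread among sets. In the plain mean of 3 arrays, 1012 reached 2-fold, 340 higher and 672 lower, so that 66.4% were lower. The dye component reached 2-fold on 1846 probes and was positive on 1485 of them.

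The authors' deposited table of combined ratios was set beside these values. In the authors' deposited table, 1294 of the tested probes reached 2-fold, 383 higher and 911 lower, so that 70.4% were lower. Of those 1294 in the authors' deposited table, 691 (53.4%) had equal signs on all 3 arrays, 259 higher and 432 lower. Another 551 (42.6%) took the sign of sets 2 and 3 while set 1 was opposite, and 470 of these 551 were lower in ap1 in the authors' deposited table.

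**Figure D3:**
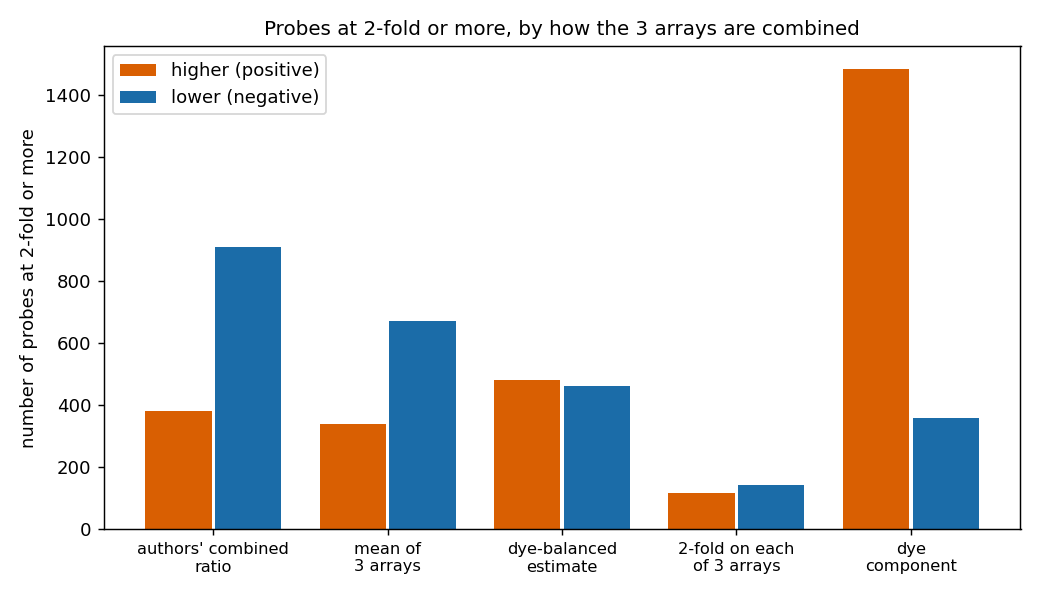
Number of probes at 2-fold or more with positive (orange) and negative (blue) values in the authors' combined ratio, the mean of 3 arrays, the dye-balanced estimate, on each of the 3 arrays, and in the dye component. Negative values outnumber positive ones in the authors' combined ratio (911 against 383) and the plain mean (672 against 340), but not in the dye-balanced estimate (462 against 483).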

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

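The count of 0 probes past the adjusted threshold also held with the dye term, centring, scaling, robust eBayes, the test against 1.2-fold, an adjusted p under 0.01 or 0.1 in the main fit, ratios on at least 2 arrays, and exact zeros kept. With 1 set left out it ran from 0 to 1894, the latter without set 1. Array weights, which gave set 1 a weight of 0.241 against 1.36 and 3.06, called 1587 probes, and the dye term with an adjusted p under 0.1 gave 2183, with an error from sets 2 and 3 alone. Probes under 0.05 before adjustment numbered 3308. They were 6112 with the dye term, 1604 against 1.2-fold, 8922 with array weights, and 1059 to 7675 with 1 set left out. Sets 1 and 2 alone, a balanced dye swap on slide 1, gave 1059, with 0 past the adjusted threshold, and slide 2 held 1 array and allows no test. Of the 3308, 1519 were higher and 1789 lower. The majority turned to higher with the dye term (3356 higher and 2756 lower) and with exact zeros kept (2357 and 1791). Lower probes led otherwise, as after centring (1268 and 1981) and scaling (1280 and 1947). The 263 probes at 2-fold on every set became 365 to 1673 with 1 set left out, the highest without set 1. With fewer sets required, this count can only stay or rise. It was 268 and 267 after centring and scaling. If the deposited values were log2, 2 probes would remain at 2-fold on every set and 7 in the authors' combined ratio. Rank correlations were -0.0782 for sets 1 and 2, -0.0153 for sets 1 and 3 and 0.740 for sets 2 and 3, and with exact zeros kept Pearson's r was -0.139, -0.0824 and 0.717. Each of the 4 named probes kept its sign under its 11 alternatives. Their choice for large means of 1 sign on all sets made this nearly certain. Their means ran from -4.98 to -4.56, -5.35 to -3.53, 2.70 to 4.05 and 3.11 to 4.06 in report order. Of these values, 37 stayed on the same side of the threshold and 7 passed it, all without set 1 or with array weights. Adjusted p-values of the named probes ran from 0.0371 to 1. Slide as a random block could not be fitted (no estimable correlation). A filter on signal, a variance trend and a test of the authors' p-values were not run, as the tables used here hold neither signal nor p-values. AP1 and the gene lists were not tested. Causes of the other shifts were not tested.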

Other observations

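All tests of explanations below were chosen after the values were seen. The probe identifiers fall into a larger series of 26566 probes and a smaller one of 6049, and what either targets is not given in the sources used here. In the larger series 81.6% of probes had a ratio on all 3 arrays, and in the smaller series 24.7%. At least 2-fold differences of 1 sign on every set occurred in 255 of 21682 measured probes of the larger series (1.18%) and in 8 of 1492 of the smaller (0.536%). Across the smaller series sets 2 and 3 correlated at 0.805, and set 1 ran against them at -0.702 and -0.631. Across the larger series the corresponding values were 0.761, -0.0520 and 0.0189. A dye component of at least 2-fold was found for 22.3% of the 1492 measured probes of the smaller series, with 114 positive and 219 negative, and for 6.98% of the 21682 of the larger, with 1371 positive and 142 negative.

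Sets 2 and 3 agreed while set 1 ran against them in the smaller probe series and was nearly unrelated to them in the larger one. Ratios left as dye over dye are argued against by the control spots. Of the control rows other than spike-ins, 79.3% (exact 95% interval 60.3 to 92.0%) had set 1 opposite in sign. The interval counts rows as independent, though some rows of like name had alike values, so it is too narrow. A slide difference is argued against as well, because sets 2 and 3 lay on different slides and their r exceeded that of sets 1 and 2, on the same slide, by 0.896 over all probes and by 0.813 in the larger series. Independent noise in set 1 leaves covariances as they are, but that of sets 2 and 3 exceeded the mean covariance of set 1 with them by 0.322 log2 squared in the larger series (95% interval 0.307 to 0.336) and by 1.17 in the smaller (1.07 to 1.26). A dye effect left in the deposited ratios, seen in those control rows as a median dye component of -0.75 log2 but with the opposite sign to most 2-fold dye components of probes, and a difference in the plants or day of set 1 cannot be told apart for the probes, because only 1 array had ap1 in Cy5.

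Of the 1894 probes called from sets 2 and 3 alone, set 1 was opposite in sign for 55.7% (exact 95% interval 53.4 to 58.0%). Among all tested probes with equal signs on sets 2 and 3, set 1 was opposite for 9044 and not for 9315. In set 1, 234 of the 1894 differed by at least 2-fold in the same direction and 586 in the opposite one. No explanation was tested for this split.

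Falls made up 70.4% of probes at 2-fold in the authors' combined ratios. This excess may come in part from the 2 of 3 arrays that share a dye orientation. Falls also led where set 1 agreed in sign. Among the combined 2-fold probes with equal signs on all 3 arrays, 432 of 691 were falls. These were picked by the combined ratio, so the share can carry the greater weight of sets 2 and 3 in it. Falls were 144 of the 263 probes at 2-fold on every array (54.8%) and 22 of the 30 at 4-fold (73.3%). No interval was computed for these shares, so they do not decide on the explanation. With both orientations weighed equally, falls made up 48.9% at 2-fold and 49.2% at 4-fold, where the combined ratios had 67.7%. They made up 66.7% of the 27 probes at 8-fold (exact 95% interval 46.0 to 83.5%), too few to decide for the largest changes, where 18 of 21 combined values were falls. Weighing orientations equally also gives set 1 more weight, so a difference in its plants or day stays open here too. Among the 551 probes with set 1 opposite, 85.3% were falls. Their combined value lay a median of 0.04 log2 from the mean of sets 2 and 3 and 0.83 from the mean of all 3 arrays. The median size of their dye-balanced estimate was 0.30, against 1.41 for the combined value. These probes were picked for a combined value of at least 2-fold on the side of sets 2 and 3. A small dye-balanced size and some closeness to sets 2 and 3 follow from that choice, so neither bears on the explanation.

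The 3 arrays allow 4 assignments of sign, the real one included, too few for a share under 0.05. For probes past the adjusted threshold all 4 splits gave 0, the highest other included. Their smallest adjusted p in the main limma test was not alike. It was 0.236 for the real split and 0.0564 with set 1 turned. With set 2 or set 3 turned it was 0.99992 and 0.99995. For probes under 0.05 before adjustment 2 of the 4 splits gave as many as the real 3308, and the highest other was 3485. For 2-fold differences on every array 2 of the 4 gave as many as the real 263, and the highest other was 597. In both cases the highest other was the split with set 1 turned, which aligns the arrays by dye instead of by sample.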
